A study of Homo sapiens with 6 samples.

How the data were processed

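HEK293 cells, an established line derived from human embryonic kidney, were left untreated or were given sodium salicylate at 50 mM for 30 or 60 min, per the labels. Salicylate is the active breakdown product of aspirin. Total RNA of each sample was reverse transcribed with a primer that carries an oligo(dT) stretch and a T7 promoter, amplified to biotinylated cRNA and hybridised to an Illumina human bead array, per the labels' protocols. There were 2 arrays in each of 3 groups, 6 in all. The labels do not say whether the 2 samples of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

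The authors deposited a table with the intensity of 47323 probes on each array, on a linear scale and not normalized, and a detection p-value beside each intensity. In every array the detection p-value fell, or stayed level, with each step up in that array's own intensity (100% of steps), against at most 67.2% of steps when it was set against another array's intensity. The deposited series table holds the authors' processed values on the log2 scale. They differed by at most 5e-07 from the log2 of the deposited intensities after quantile normalization with no background correction, and the median of every column was 7.19. GenomeStudio 2011.1 and R 2.15.3 are named in the submitters' processing notes. No value column was left unmatched to a sample.

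Intensities were corrected for background with the normexp method of limma, with the negative controls inferred from the detection p-values (the neqc method, offset 16), then quantile normalized and taken to log2. A probe was kept if its detection p-value was under 0.05 on at least 2 of the 6 arrays, which left 22377 probes. Gene names came from the platform annotation given for the probes, updated through the gene identifier to the RefSeq names of the GRCh38.p14 annotation; no coordinates were used. Of all probes, 30113 had 1 gene symbol, 8 had several and 17202 were not named by the table used here. Of the 20047 genes with a probe, 20020 were found by identifier in the RefSeq table. Each gene was represented by the detected probe with the highest mean over the 6 arrays, which gave 12547 genes, of which 3293 had more than 1 detected probe.

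All 6 arrays were fitted together with limma 3.58.1 in R 4.3.3, with a mean for each group. The 3 comparisons were taken as contrasts, with moderated variances that follow the trend with intensity. Adjusted p-values are Benjamini-Hochberg values over all genes tested, and a gene is said to have risen or fallen where this value was under 0.05. The fit had 3 residual degrees of freedom and a prior of 8.92. The spread was pooled over the 3 groups. Values are log2 differences between group means of normalized intensity, with the standard error of the fit (SE). Array intensities compress large changes, so a fold given here is a fold of normalized intensity. The number of arrays limits the precision, and the median SE over genes was 0.0918.

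A gene with a detection p-value of at least 0.05 in all its probes on both arrays of a group was taken as not above background there. Its change is given as "at least" a fold. This is the mean of the brighter group against, on each array of the dimmer group, the higher of the lowest detected signal and the gene's own value. Such a bound holds for background-corrected values only, since the changes of many genes are smaller without the correction.

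In tests on simulated data for the 12547 genes, 200 were changed by known amounts. For 30 min against control, 92.4% of genes changed by 1 on the log2 scale were called, as were 71.6% of those changed by 0.5 and 19.4% of those changed by 0.25. The corresponding shares for 60 min against control were 100%, 73.1% and 26.9%. For 60 min against 30 min they were 92.4%, 68.7% and 19.4%. Among unchanged genes the false calls in the 3 comparisons numbered 6, 18 and 11. In the last 2 comparisons they made up more than 0.05 of the calls. In the data far more than 200 genes passed the threshold at 60 min (2870 against control). At 30 min 41 passed, fewer than the 61 called in the simulation among genes changed by 1 alone. The adjusted threshold is stricter where fewer genes pass. The simulated noise was also drawn separately for each gene and array, with no effect of an array as a whole. The shares called in the simulation therefore do not give the sensitivity at either time.

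Before the data were examined, 40 gene lists were fixed (pathways, complexes, RNA classes and markers of other cell types). The 35 lists with at least 5 tested members were compared with all other genes by camera, a limma test that allows for correlation within a list, at a preset correlation of 0.01. The 105 tests (35 lists in 3 comparisons) were adjusted together. No call was kept when camera estimated the correlation from the data. That version takes its p-value from the 3 residual degrees of freedom, and its lowest adjusted p was 0.525. Over the called lists the estimated correlation ran from -0.105 (Notch targets) to 0.27 (BMP and TGF-beta targets, and CREB targets). It was 0.117 for NFAT5 targets and 0.0658 for ribosomal protein genes. Where it lay above 0.01, the preset value may make the p-values of camera too small. Fry, a second limma test planned for the lists, asks whether members change together without a comparison with other genes. It was adjusted over the same 105 tests. Counts of members use the adjustment over all genes, and a second count is given "adjusted over the list alone". The genes named were also fixed by rule: in each comparison the 12 largest rises and 12 largest falls among genes past the threshold whose arrays did not overlap between the groups, and up to 4 members of each list with the largest change at 60 min against control, those past the threshold first. All measured members of a list of proteins reported to bind or transport salicylate could be named. Symbols that are only clone or locus names were counted and not named.

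Alternatives covered the background correction, the normalization, the authors' processed values, the filter on dim probes, the choice of probe, the variance model, the arrays in the fit, the replicate number as a block, a minimum change of 2-fold and the omission of each array in turn.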

Results

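Gene expression was measured on Illumina bead arrays in HEK293 cells left untreated or given 50 mM sodium salicylate for 30 or 60 min, with 2 arrays in each of the 3 groups. The design asks which transcripts change within the first hour of exposure and whether the changes at 30 min go on to 60 min. No sample was labelled as mock-treated or as given another salt. Effects of handling, time or the added sodium salt therefore cannot be told apart from those of salicylate. Arrays detected between 20726 and 21740 of 47323 probes, and their median intensity lay between 143.1 and 147.6. Over the 12547 genes tested, the values of any pair of arrays correlated at between 0.99057 and 0.99681 across genes. The first principal component held 49.6% of the variance and set the 60 min arrays apart from the rest. The next component held 20.3% and separated the control arrays from the 30 min arrays, with the 60 min arrays on opposite sides of it.

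After 30 min of salicylate the largest rises were in short structural RNAs. RNA5S9, a gene for the 5S RNA of the ribosome, was 9.4-fold above control (log2 change 3.23 ± 0.066, SE, n = 2 arrays per group, adjusted p = 5.5e-11). The U3 small nucleolar RNA genes SNORD3D, SNORD3C and SNORD3A, whose product takes part in processing the precursor of ribosomal RNA, rose by log2 changes of 1.68 ± 0.11, 1.47 ± 0.10 and 1.23 ± 0.09. RMRP, the RNA of the RNase MRP enzyme, was not above background in the controls and was at least 2.26-fold higher at 30 min (adjusted p = 0.00138), with a log2 change of 1.42, or 0.64 without background correction. RPPH1, the RNA of RNase P, rose by 0.98 ± 0.12. SNORA57, SNORD99 and RNU11, the RNA of the minor spliceosome's U11 particle, rose by 1.55, 1.00 and 1.04. The calls of RPPH1, SNORD99 and RNU11 were lost without either control array, and the last 2 also without 30 min replicate 2 (highest adjusted p 0.0854, 0.154 and 0.131 over 10 settings). Among protein-coding genes, the stress-inducible growth arrest genes GADD45G and GADD45B rose by 1.27 ± 0.11 and 0.94 ± 0.08, or 2.42-fold and 1.91-fold. HINT3 rose by 1.31, but a second detected probe of this gene changed by 0.036. The U3 genes are near-identical copies and 5S genes are repeated many times in the genome, so a probe named for one copy may have measured others.

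Several of the largest falls at 30 min were in other small RNAs. SNORA12, at least 2.83-fold lower (adjusted p = 0.00379), was not above background after treatment. Its log2 change was -1.78, or -0.83 without background correction. SNORD4A, SNORD38A, SNORD31, SNORA18 and SNORD14A had log2 changes of -1.27 ± 0.19, -1.21 ± 0.18, -0.95 ± 0.14, -0.86 ± 0.13 and -0.72 ± 0.12. All 5 calls were lost without either control array and without 30 min replicate 1 (highest adjusted p 0.224, 0.244, 0.169, 0.213 and 0.288 over 10 settings). SCARNA22, a small RNA of Cajal bodies, changed by -0.88 ± 0.15. NOG, which encodes the secreted BMP antagonist noggin, changed by -1.07 ± 0.19. The rhomboid protease gene RHBDL2 changed by -1.37 ± 0.17 on the probe used, while its other detected probe stayed at -0.00285. LINC01018, AOC4P and TCAF2 changed by -0.82, -0.83 and -0.72. The calls of RHBDL2, AOC4P and TCAF2 were lost without either control array, and that of TCAF2 also without 30 min replicate 1 (highest adjusted p 0.0995, 0.169 and 0.275). HMOX1, which encodes the haem-degrading enzyme haem oxygenase 1, fell by 0.66 on the log2 scale (adjusted p = 0.00976), a call lost without control replicate 1 or 2 or 30 min replicate 2 (range 0.000511 to 0.195 over 10 settings).

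In all, 41 of the 12547 genes passed the threshold at 30 min, 19 higher and 22 lower, and 15 of them changed by at least 2-fold. The count and its split depended on single arrays: 11 genes without control replicate 1 (10 higher, 1 lower), 15 without control replicate 2 (13 higher, 2 lower), 26 without 30 min replicate 1 (17 higher, 9 lower), 61 without 30 min replicate 2 (15 higher, 46 lower), 167 without 60 min replicate 1 and 162 without 60 min replicate 2. With median scaling 27 were higher and 57 lower. Without background correction the log2 changes of 14 of the 24 genes named by size were smaller by over 1.5 times. Of the 24 genes named by size, 11 kept their call in every setting in which they were tested (8 settings for SNORA12). Omission of control replicate 1 or 2 ended 13 calls each, of 30 min replicate 1 ended 8 and of 30 min replicate 2 ended 5, all without a change of direction. The replicate number as a block ended 2, NOG and SCARNA22, each of which was lost in 5 of 10 settings (adjusted p from 4.64e-05 to 0.397 and from 0.00154 to 0.417).

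**Figure D1:**
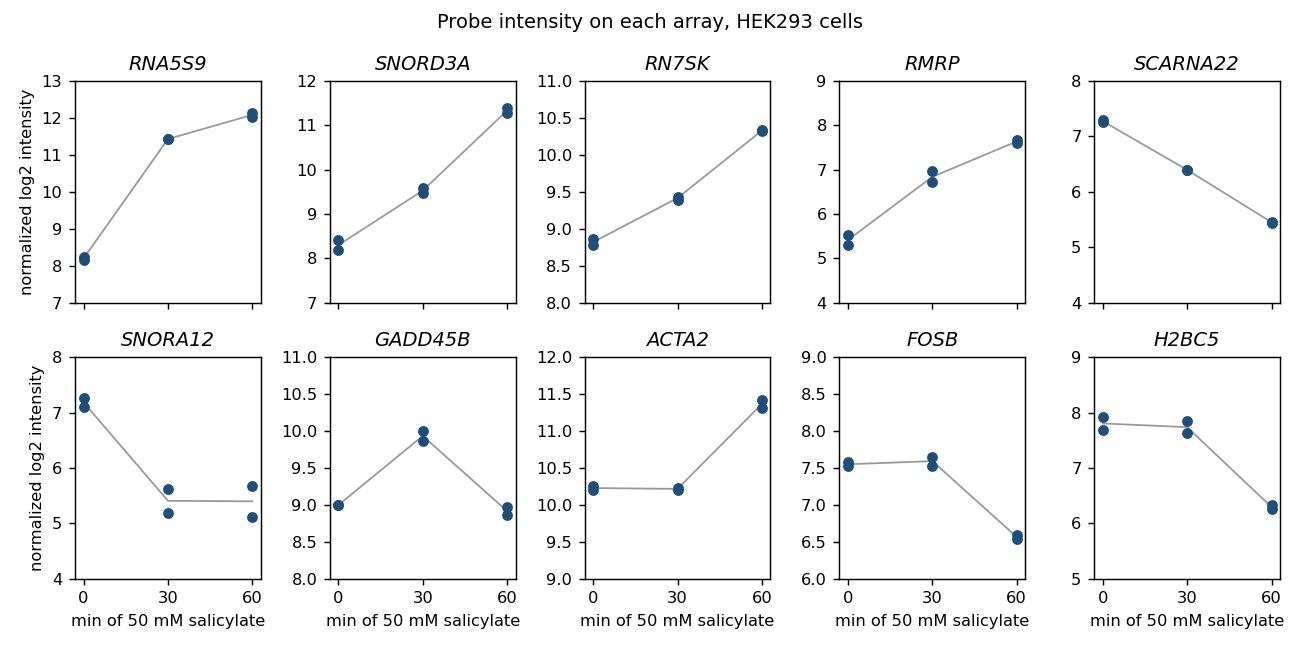
Normalized log2 probe intensity (vertical axis, a separate range in each panel) against min of 50 mM salicylate (horizontal axis, 0 for untreated cells) for 10 genes. Each point is 1 array, and lines join the means of 2 arrays. RNA5S9, SNORD3A, RN7SK and RMRP were higher at each later time, SCARNA22 was lower, SNORA12 had fallen by 30 min, GADD45B was high at 30 min alone, and ACTA2, FOSB and H2BC5 changed between 30 and 60 min.

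At the level of gene lists, 3 of the 35 lists tested stood apart from other genes at 30 min, all upward. Of 17 measured snoRNA host genes and nuclear noncoding RNAs, 3 rose and 0 fell (6 and 1 adjusted over the list alone; camera adjusted p = 1.02e-05). With an estimated correlation the adjusted p was 0.525. The 3 that rose, RMRP, RPPH1 and RN7SK, are not hosts of snoRNAs; RN7SK, the 7SK RNA that holds the elongation factor P-TEFb inactive, rose by 0.60 ± 0.07, a call lost without control replicate 1 (adjusted p = 0.0854, range 0.00102 to 0.0854 over 10 settings). Of 73 cytosolic ribosomal protein genes 0 passed the threshold, over all genes or adjusted over the list alone. Their median log2 change was 0.0535 (camera adjusted p = 0.0081, and adjusted p = 0.575 with an estimated correlation). Of 19 HIF1 targets, known for their response to low oxygen, 1 rose and 0 fell (2 and 0 adjusted over the list alone), with a median of 0.0595 (camera adjusted p = 0.0091, and adjusted p = 0.525 with an estimated correlation). The riser was ADM, which encodes the vasodilator peptide adrenomedullin, at 0.49 ± 0.06. ADM lay outside the rule for naming genes, and its call was not run in the other settings. By fry the adjusted p was 0.0167 for the noncoding list, 0.17 for ribosomal protein genes and 0.0764 for HIF1 targets. The hypoxia call was lost without control replicate 1 (adjusted p = 0.142, range 0.00182 to 0.142 over the 6 omissions), and its median was 0.0898 without control replicate 2. The ribosomal call was lost without control replicate 1 (0.0864) and without 30 min replicate 1 (0.0942, range 0.00274 to 0.0942), where the median was 0.0179.

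Within the list of small nucleolar and spliceosomal RNAs, 7 of 116 measured members rose and 8 fell at 30 min (14 and 20 adjusted over the list alone). The median was -0.0503 and the list did not stand apart in 1 direction (camera adjusted p = 0.496).

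After 60 min the same short RNAs led the rises, and many more genes had changed. RNA5S9 was 14.8-fold above control (log2 change 3.89 ± 0.066, adjusted p = 6.17e-12). SNORD3D, SNORD3C and SNORD3A were 12.8-fold, 10.8-fold and 8.19-fold higher, with an adjusted p of 1.09e-09 for each. RMRP was at least 3.93-fold higher (adjusted p = 1.05e-05), SNORA57 3.28-fold, RN7SK 2.85-fold and RPPH1 2.56-fold. The vault RNA gene VTRNA2-1 rose by 1.54 ± 0.20. VTRNA1-1 was not above background in the controls and was at least 1.89-fold higher (adjusted p = 0.000644). RNA28SN5, a gene for the 28S RNA of the ribosome, rose by 1.79 ± 0.19, with 0.90 on its other probe. HINT3 rose by 1.34 on the probe used and changed by 0.212 on the other.

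The largest falls at 60 min included several small RNAs, H2BC5, TADA2B, P2RY11 and GPER1. SCARNA22 and SNORA12 were not above background at 60 min and were at least 2.98-fold and 2.79-fold lower (adjusted p = 4.36e-05 and 0.000457). SNORD14C and SNORA3B changed by -1.10 ± 0.17 and -1.04 ± 0.15, and SNORD84, not above background at 60 min, was at least 1.79-fold lower (adjusted p = 0.00287). H2BC5, a histone H2B gene, changed by -1.51 ± 0.13, and TADA2B, which encodes an adaptor of the SAGA histone acetyltransferase complex, by -1.24 ± 0.09. P2RY11, a receptor for extracellular ATP, changed by -1.13 ± 0.08. GPER1, a G protein coupled receptor for oestrogen, changed by -1.11 ± 0.10, and its 3 detected probes all had negative changes, the smallest -0.355. RHBDL2, RANBP3L and ESS2 changed by -1.28, -1.17 and -1.06. The other detected probes of these genes lay at -0.102, -0.863 and -0.00134, so RHBDL2 and ESS2 rest on 1 probe each.

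In all, 2870 genes passed the threshold at 60 min, 1322 higher and 1548 lower. The median size of their change was 0.358 on the log2 scale, and 37 changed by at least 2-fold (21 higher, 16 lower). All 24 genes named by size kept their call in every setting in which they were tested. Their size depended on the background correction: without it, 13 of the 24 log2 changes were smaller by over 1.5 times, among them those of RMRP (1.10 in place of 2.22), SCARNA22 (-0.86 in place of -1.82), SNORA12 (-0.85 in place of -1.79) and H2BC5 (-0.84 in place of -1.51). The balance of higher and lower genes depended on the scaling: with medians in place of quantiles, 404 genes were higher and 1250 lower, while the median over all genes moved to -0.0596. The count was 1355 without control replicate 1 and 1230 without control replicate 2.

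Many immediate early genes fell at 60 min. These genes are transcribed within minutes of a stimulus and give short-lived transcripts. Of 42 measured members of the list, which also holds feedback regulators of MAP kinases, 20 fell and 1 rose (22 and 1 adjusted over the list alone). The median was -0.278 (camera adjusted p = 2.97e-05, and adjusted p = 0.525 with an estimated correlation), and it was -0.177 without 60 min replicate 2. FOSB changed by -0.98, the kinase gene SGK1 by -0.65 and TRIB1 by -0.65. MYC, named for the Wnt target list, changed by -0.53 (SE 0.055). The C2H2 zinc finger genes, mostly transcriptional repressors, had more members lower than higher. Of 341 measured, 84 fell and 12 rose (89 and 13 adjusted over the list alone), with a median of -0.143, or -0.221 with median scaling (camera adjusted p = 0.00011, and adjusted p = 0.525 with an estimated correlation). ZNF618 and ZNF490 changed by -0.79 and -0.75. ZNF540, not above background at 60 min, was at least 1.62-fold lower (adjusted p = 0.00346), whereas ZNF687 went the other way at 0.78 (adjusted p = 0.0113), a call lost without either control array or 60 min replicate 2 (range 0.00178 to 0.0906 over 10 settings). Of 17 genes that control transcription by RNA polymerase II, 8 fell and 0 rose (9 and 1 adjusted over the list alone; median -0.213). The camera adjusted p was 0.00438, and the adjusted p was 0.525 with an estimated correlation. MEPCE, which caps and stabilises 7SK RNA, changed by -0.54 and SERTAD2 by -0.73. These 3 calls and their directions held under every scaling tried and without any single array.

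Smaller lists of regulators also lay below other genes at 60 min, with calls that single arrays or other settings could end. Of 20 genes of mRNA decay and stress granules 5 fell and 0 rose (6 and 0 adjusted over the list alone; median -0.151). ZFP36L2 and TOB1, which promote deadenylation, changed by -0.89 and -0.72. Of 13 early targets of BMP and TGF-beta 6 fell and 1 rose (7 and 1 adjusted over the list alone; median -0.351), with SKI at -0.64 and ID2 at -0.39. Of 9 CREB targets 4 fell and 0 rose, over all genes and adjusted over the list alone (median -0.168). FOSB and NR4A2 lie in both this list and the immediate early one. Of 8 Notch targets 4 fell and 0 rose (6 and 0 adjusted over the list alone; median -0.209), with HEYL at -0.48. Of 8 NFAT5 targets, known for their response to osmotic stress, 3 fell and 0 rose (4 and 0 adjusted over the list alone; median -0.335), with the inositol transporter gene SLC5A3 at -0.67. In this order the camera adjusted p was 0.0256, 0.0307, 0.0449, 0.0492 and 0.0496. Fry gave an adjusted p of 0.0167, 0.0747, 0.0747, 0.00981 and 0.052. With an estimated correlation the camera adjusted p was 0.525, 0.605, 0.594, 0.541 and 0.575. Omission of 1 array raised the adjusted p to at most 0.059 (without control replicate 2), 0.116 (without 60 min replicate 2), 0.129 (without control replicate 2), 0.113 (without 60 min replicate 1) and 0.0797 (without control replicate 2), from lowest values of 0.0192, 0.0117, 0.0229, 0.0466 and 0.0341. The median was -0.258 for CREB targets without control replicate 1 and -0.204 for NFAT5 targets without 60 min replicate 2. With the replicate number as a block the NFAT5 and Notch calls were lost (adjusted p = 0.0502 and 0.0579), and the Notch call was also lost with median scaling (0.0988) and cyclic loess (0.0529), in 8 of 12 settings in all (range 0.0466 to 0.541). The median of the mRNA decay list was -0.231 with median scaling, and that of the BMP and TGF-beta list -0.223 without background correction.

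Lists of abundant housekeeping transcripts and of mitosis moved upward at 60 min by small amounts. Of 22 genes of G2 and mitosis 5 rose and 0 fell (7 and 0 adjusted over the list alone; median 0.147). CENPE, a kinetochore motor, rose by 0.47 and HMMR by 0.45 (camera adjusted p = 0.000387, and adjusted p = 0.525 with an estimated correlation). Of 14 sterol synthesis genes 5 rose and 0 fell, over all genes and adjusted over the list alone (median 0.155, and 0.251 without control replicate 2), with HMGCS1, a synthase of the mevalonate pathway, up by 0.46. The camera adjusted p was 0.00192, and the adjusted p was 0.525 with an estimated correlation. Of 73 cytosolic ribosomal protein genes 16 rose and 2 fell, both over all genes and adjusted over the list alone (median 0.0728, and 0.124 with median scaling). RPL39L rose by 0.62 and RPL14 by 0.55 (camera adjusted p = 0.000431, and adjusted p = 0.575 with an estimated correlation). Of 74 subunit genes of the respiratory chain 7 rose and 0 fell (6 and 0 adjusted over the list alone; median 0.0652), with NDUFA7 and NDUFV1 at 0.35 and 0.32, both calls lost with median scaling (ranges of adjusted p 0.00179 to 0.0967 and 0.00281 to 0.109 over 10 settings). Their camera adjusted p was 0.0091, the adjusted p was 0.575 with an estimated correlation, and the fry adjusted p was 0.0747. This last call was lost without control replicate 2 (adjusted p = 0.0598, range 0.00418 to 0.0598 over the 6 omissions).

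**Figure D2:**
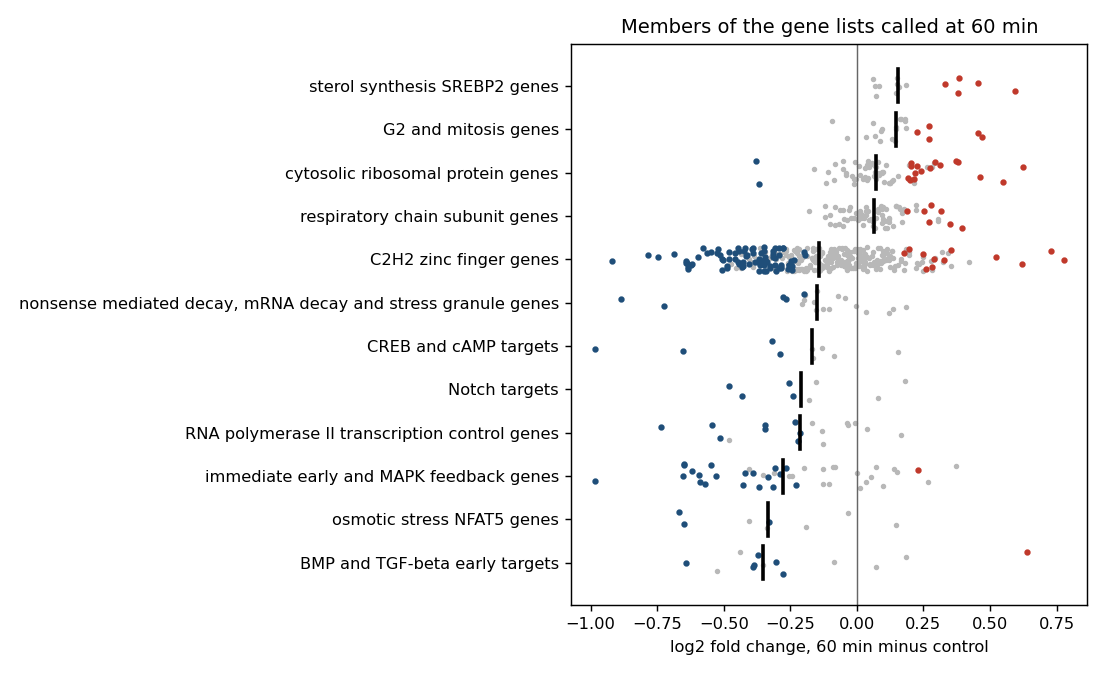
The log2 fold change at 60 min against control (horizontal axis) of each measured member of the 12 gene lists that camera called in this comparison (vertical axis; points are spread vertically only to part them). Red and blue points are members past the threshold, higher and lower, grey points are the others, and black bars are the list medians, from -0.351 for BMP and TGF-beta targets to 0.155 for sterol synthesis.

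Several stress programmes named by the other lists did not stand apart from other genes by camera at 60 min. By fry the adjusted p was 0.046 for the NRF2, 0.0399 for the metallothionein and 0.0167 for the glucocorticoid receptor list. It was at least 0.0755 for the other lists of this paragraph. Of 25 HSF1 heat shock genes 2 rose and 2 fell over all genes and adjusted over the list alone (camera adjusted p = 0.976). Of 27 ATF4 genes of the integrated stress response 2 rose and 6 fell (4 and 7 adjusted over the list alone; 0.881), with CEBPB at -0.37 and PPP1R15A at -0.36. Of 17 genes of the unfolded protein response 1 rose and 2 fell by both adjustments (0.94), HSP90B1 being the riser at 0.29. Of 18 NF-kappaB targets 4 rose and 3 fell by both adjustments (0.778). Within this list CCL2 and NFKB1 changed by -0.96 and -0.47, and CCL20, not above background in the controls, was at least 1.45-fold higher (adjusted p = 0.0154), a call lost without control replicate 1 (0.13, range 0.00183 to 0.13 over 8 settings). Of 14 NRF2 genes 0 rose and 5 fell by both adjustments (0.253), with SRXN1 at -0.38. Of 16 p53 targets 1 rose and 1 fell by both adjustments (0.525), the riser being the cyclin-dependent kinase inhibitor gene CDKN1A at 0.42. Of 5 metallothionein and zinc export genes 2 rose and 0 fell (3 and 0 adjusted over the list alone; 0.256), with MT1F at 0.56. HIF1 targets, called at 30 min, had 4 rising and 1 falling at 60 min by both adjustments (0.282), with ANKRD37 at 0.85. Of 9 glucocorticoid receptor targets 1 rose and 4 fell (1 and 5 adjusted over the list alone; 0.154), with TSC22D3 at -0.82.

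Among metabolic lists, 1 of 6 MondoA targets rose and 1 fell by both adjustments (camera adjusted p = 0.73), the riser being TXNIP, the thioredoxin interacting protein gene, at 0.53. Of 12 genes of mitochondrial biogenesis and uncoupling 2 rose and 1 fell (2 and 2 adjusted over the list alone; 0.976), with the mitochondrial carrier gene UCP2 at 0.84. Of 19 AMPK, autophagy and lysosome genes 3 rose and 1 fell (2 and 1 adjusted over the list alone; 0.778). Of 7 measured genes whose proteins are reported to bind or transport salicylate, 1 rose and 2 fell by both adjustments (0.588). The acetyltransferase genes CREBBP and EP300 changed by -0.40 and -0.38, and PRKAB1, a subunit of AMP-activated kinase, by 0.26. The cyclooxygenase gene PTGS2 was at -0.35, HMGB1 at -0.12, GAPDH at 0.03 and IKBKB at 0.02, and these 4 did not pass. The CREBBP call was lost without control replicate 2 (adjusted p = 0.0594, range 0.00272 to 0.0594 over the other settings), the EP300 call in 4 of 10 settings (0.00167 to 0.302, with log2 changes from -0.59 without 60 min replicate 1 to -0.16 without 60 min replicate 2) and the PRKAB1 call in 7 (0.0427 to 0.508).

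The remaining lists tested at 60 min had no call from camera, and each count is the same by both adjustments unless another is given. These were interferon stimulated genes (2 of 13 rose and 1 fell), G1/S and DNA replication (3 of 18 rose and 3 fell, or 3 and 5 adjusted over the list alone), Wnt targets (1 of 11 rose and 3 fell), YAP and SRF targets (1 of 14 rose and 1 fell, or 0 and 0), circadian clock genes (0 of 12 rose and 2 fell, or 0 and 1, with CRY1 at -0.55), proteasome subunits (2 of 31 rose and 1 fell, or 1 and 1) and histone genes (2 of 30 rose and 3 fell, H4C12 up by 0.83). The list of snoRNA hosts and nuclear noncoding RNAs had 5 of 17 higher and 3 lower (6 and 4 adjusted over the list alone). Its median was -0.00266, while its mean was 0.25. Fry gave an adjusted p of 0.0197 for this list, 0.0286 for circadian clock genes and 0.0485 for interferon stimulated genes. It gave at least 0.111 for the other lists tested in this paragraph. Small nucleolar and spliceosomal RNAs had 11 of 116 higher and 14 lower. Among markers of other cells, 1 of 7 neuronal genes rose and 1 fell (2 and 2 adjusted over the list alone), with NEFL at 0.33 (lost in 2 of 10 settings, adjusted p from 0.00669 to 0.217) and SYP at -0.51 (lost in 3, 0.00789 to 0.117). Of 4 fibroblast genes 1 rose (2 adjusted over the list alone): LUM was not above background in the controls and was at least 1.52-fold higher (adjusted p = 0.0314, lost in 2 of 8 settings, range 0.0321 to 0.117). Of 3 blood genes 1 fell, CD14 at -0.31 (lost in 7 of 10 settings, adjusted p from 0.0426 to 0.243), of 3 hepatocyte genes 0 passed, and of 3 keratinocyte or cervical genes 1 rose, EPCAM at 0.24 (lost in 3 of 10 settings, 0.00852 to 0.145). No gene of the mitochondrial genome was tested.

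Between 30 and 60 min the U3 genes, a 28S gene, LOX and ACTA2 were among the genes that rose most. SNORD3D, SNORD3C and SNORD3A were 4-fold, 3.88-fold and 3.5-fold higher at 60 than at 30 min (log2 changes 2.00 ± 0.11, 1.96 ± 0.10 and 1.81 ± 0.09). RNA28SN5 rose by 1.89 ± 0.19. LOX, the enzyme that cross-links collagen and elastin, and ACTA2, smooth muscle actin, rose by 1.17 ± 0.11 and 1.15 ± 0.06, and MEGF6 by 1.08. VTRNA1-1 and SLC67A1, not above background at 30 min, were at least 1.86-fold and 2.11-fold higher (adjusted p = 0.0013 and 0.00091). SNORD4A rose by 1.13 ± 0.19, to 7.29 against 7.43 in the controls. PPP3R1 and TAF15 rose by 1.46 ± 0.34 and 1.12 ± 0.28 with a wide spread at 60 min (SD 1.1 and 0.89). Both calls were lost without 30 min replicate 1 (adjusted p = 0.0747 and 0.0856), and the changes ran from 0.69 to 2.23 and from 0.49 to 1.74 over the omissions of a 60 min array.

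The falls between the times included genes induced by stress or stimuli. H2BC5 changed by -1.44 ± 0.13, and FOSB and FOS, subunits of the AP-1 transcription factor, by -1.03 ± 0.12 and -0.97 ± 0.15. GADD45B changed by -1.02 ± 0.08, which returned it to within 0.08 of its mean in the controls. P2RY11, JADE2, GPER1 and FOXD4 changed by -1.07, -1.05, -1.03 and -0.95. LSMEM1 and MINAR1 changed by -1.07 and -1.01. ESS2 changed by -0.95 on the probe used and by 0.00533 on the other, and 1 of the 3 detected probes of GPER1 was at 0.147.

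In this comparison 2841 genes passed the threshold, 1368 higher and 1473 lower, and 34 changed by at least 2-fold (25 higher and 9 lower). With median scaling 443 were higher and 1221 lower. Without background correction the log2 changes of 11 of the 24 genes named by size were smaller by over 1.5 times. The count was 1459 without 30 min replicate 1 and 1327 without 30 min replicate 2. Camera called 9 lists, each in the direction it had at 60 min against control. Zinc finger genes had 93 lower and 6 higher (112 and 10 adjusted over the list alone; median -0.177, camera adjusted p = 3.54e-06, and adjusted p = 0.525 with an estimated correlation). Immediate early genes had 19 lower and 1 higher (20 and 1 adjusted over the list alone; median -0.225, camera adjusted p = 5.72e-06, and adjusted p = 0.525 with an estimated correlation). The polymerase II list had 5 lower and 0 higher (7 and 0 adjusted over the list alone; camera adjusted p = 0.00262), and sterol synthesis 4 higher and 0 lower (6 and 0 adjusted over the list alone; camera adjusted p = 0.00407). With an estimated correlation the adjusted p was 0.525 for both, and no single array ended the calls of these 4 lists. The other 5 were CREB targets (camera adjusted p = 0.0256), G2 and mitosis (0.00955), mRNA decay, NFAT5 targets and ribosomal proteins (0.0492 each). Fry gave an adjusted p of 0.0747, 0.0479, 0.0269, 0.0501 and 0.123 in this order. With an estimated correlation the camera adjusted p was 0.576, 0.525, 0.525, 0.575 and 0.61. Their counts of higher and lower members were 0 and 4, 6 and 0, 1 and 4, 0 and 4, and 7 and 1 (9 and 0 for mitosis, and the same for the others, adjusted over the list alone). Each call was lost without some single array, and that of mitosis also with median scaling (0.0588). The adjusted p over the 6 omissions ran from 0.00468 to 0.0996 for CREB, 0.0257 to 0.154 for mRNA decay and 0.0133 to 0.167 for NFAT5, highest without 30 min replicate 2. It ran from 0.00372 to 0.0753 for mitosis and 0.0258 to 0.202 for ribosomal proteins, highest without 60 min replicate 2.

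The changes at both times were set against each other, with the control arrays shared by the 2 comparisons. Of the 41 genes called at 30 min, 30 were also called at 60 min in the same direction, 14 higher and 16 lower, and 0 in the opposite direction. Independent lists of these sizes would share 2 higher and 2.71 lower genes. These 2 lists share their controls and are not independent, and no overlap was simulated with shared controls. Across genes, which are not independent replicates, the log2 changes at 30 and 60 min correlated at Pearson r = 0.37, and 59.8% had the same sign. The r was 0.465 without control replicate 2 and 0.26 without 60 min replicate 2, the extremes over the 6 omissions. Simulated groups with no effect, compared with the same controls, gave a mean r of 0.498 and 66.7% of the same sign over 100 simulations. The observed r and share of the same sign lay below these means, so neither showed more likeness than shared controls alone gave. The covariance lay above, at 0.0174 against 0.008 in the simulations. With 2 control arrays no split of the controls left a pair on each side, so part of any excess may come from the shared controls. The overlap was 10 genes without control replicate 1, 14 without control replicate 2, 106 without 60 min replicate 1 and 48 without 60 min replicate 2.

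**Figure D3:**
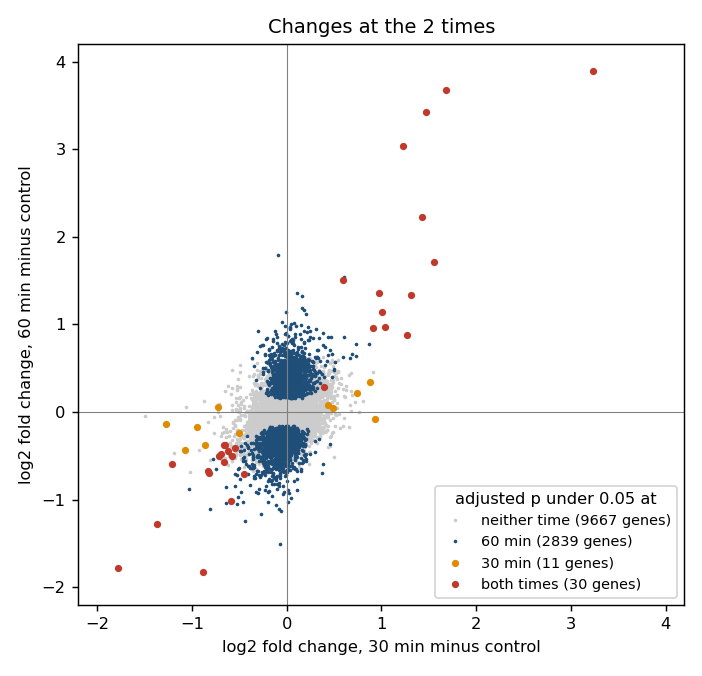
The log2 fold change against control at 60 min (vertical axis) and at 30 min (horizontal axis) for each of 12547 genes, 1 point per gene. Red points are the 30 genes past the threshold at both times, orange points the 11 at 30 min alone, blue points the 2839 at 60 min alone and grey points the other 9667. The red points lie in the quadrants where both changes have the same sign.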

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

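The tests of small RNA carry-over and of a stop in transcription were chosen after the results they bear on had been seen, as was the count of genes outside polymerase III, and the gene list of the polymerase III test was corrected after its result was seen.

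Of the 41 genes that changed at 30 min, 23 also differed between 30 and 60 min, and 16 of these had been named at 30 min. A test of the difference between the times drew attention to them. Some went further in the direction taken at 30 min. The log2 change from 30 to 60 min was 0.65 for RNA5S9, 2.00 for SNORD3D, 1.96 for SNORD3C, 1.81 for SNORD3A, 0.80 for RMRP, 0.91 for RN7SK, 0.38 for RPPH1 and -0.94 for SCARNA22. SCARNA22 was not above background at 60 min, and its change ran from -0.96 to -0.40 over 10 settings. Others moved the opposite way: GADD45G by -0.40 and GADD45B by -1.02 after a rise, and SNORD4A by 1.13, SNORD31 by 0.78, SNORD14A by 0.79, SNORA18 by 0.48, SNORD38A by 0.62 and NOG by 0.64 after a fall. These genes were picked for large values at 30 min and the same 30 min arrays enter both comparisons, so part of the movement back can follow from that choice, and the falls of these 6 at 30 min were themselves lost when 1 array was left out. The difference for RPPH1 had an adjusted p of 0.0435 and was lost in 6 of 10 other settings (range 0.0109 to 0.283), and that for RMRP in 1 of 10 (highest adjusted p 0.0512). Such settings were not run for the differences of RNA5S9, GADD45G, SNORD14A, SNORA18, NOG, SNORD31 and SNORD38A.

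Probes for which no single gene was named lay outside the comparisons of genes. Tested alone, 8 of these 5668 detected probes passed the threshold at 30 min against control, 360 at 60 min against control and 205 at 60 min against 30 min. Their largest changes at 60 min against control were 3.00 and -3.72 on the log2 scale.

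The joint rise of structural noncoding RNAs was the first pattern weighed, on the 9 genes of 2 fixed lists that were higher at both times (RN7SK, RNU11, RMRP, SNORA57, SNORD99, SNORD3A, SNORD3C, SNORD3D and RPPH1). A general carry-over of small RNA into the labelling would have raised the class together, yet 14 of the 116 measured small nucleolar and spliceosomal RNAs fell at 60 min. The choice of background correction or normalization was also argued against, since 9 of the 9 kept their call at 60 min in each of 5 other settings. Of these settings, the authors' processed values repeat the one without background correction. A rise of RNA polymerase III products cannot account for the whole pattern, since 6 of the 9 lie outside that class. For RMRP, RN7SK and RPPH1 it was left undecided. Of 8 further measured genes of that polymerase, 2 rose at 60 min (BCYRN1 by 0.54 and RNU6-1 by 0.30). RN7SL1 was at -0.29 and did not pass. These 8 were left after 6 genes named before were taken out, all 6 among the largest rises at 60 min. The count of 2 therefore cannot weigh against a rise of the class. Of all 14 tested, 8 rose and 0 fell, against 1322 higher and 1548 lower among all 12547 genes. The 14 include RMRP, RN7SK and RPPH1 themselves, with RNA5S9, VTRNA1-1 and VTRNA2-1. The first form of that list also held a protein gene by mistake, which gave 2 of 9. By the cut-off set for the test this would have counted against the class, so its formal outcome turned on this correction. Because labelling began from an oligo(dT) primer and these RNAs normally lack a poly(A) tail, a gain of adenylated forms may have raised their signal with no gain in amount, and that was not tested.

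The other pattern weighed was the fall of zinc finger and immediate early genes with the rise of ribosomal protein genes at 60 min. Compression that depends on intensity was tested against 10000 random lists matched on mean intensity. The medians of zinc finger genes (-0.143) and immediate early genes (-0.278) lay at percentile 0 of their matched lists, and that of ribosomal protein genes (0.0728) at percentile 100. This argues against intensity alone in the quantile-normalized values, on which camera had already called these lists. Little trend with intensity was left there, since the middle matched medians were -0.00837, -0.00794 and -0.00208. The test was not run with median scaling, so it does not decide the question for those values. A complete stop of transcription from the moment salicylate was added should have lowered the short-lived immediate early transcripts by 30 min, but their median change then was 0.00916. A partial or later loss of transcription, which may lower unstable transcripts before stable ones, remains a hypothesis that was not tested, since no transcript half-lives were used.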

How the results depend on the processing

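Settings added after seeing the data were the omission of small RNAs from the genes tested, the list tests with cyclic loess or no background correction, and the noncoding list without RMRP, RPPH1, RN7SK and TERC, which kept its call at 30 min (adjusted p = 0.00561, against 1.17e-06 to 0.525 over the other settings with the full list). The slide alternative was not run because no slide was given. The authors' processed values equal the setting without background correction. At 30 min against control the 41 calls became 84 with median scaling, 13 without the variance trend, 168 when only the arrays compared were fitted, 15 with a 2-fold minimum and 25 without small RNAs, and lay between 11 and 167 when 1 array was left out. At 60 min against control the 2870 calls became 1654 with median scaling, 1574 without the trend and 37 with a 2-fold minimum, and lay between 1230 and 2758 with 1 array left out. At 60 against 30 min the 2841 calls became 1664, 1551 and 34 in these settings, and lay between 1327 and 2561. The fewer calls with a 2-fold minimum follow from its construction, as does part of the loss without small RNAs. Without the trend, or with only the arrays compared, the log2 changes stay the same by construction (median -0.00407 at 30 min). Those 2 settings therefore moved the counts through the estimate of the spread alone. For the rest the cause was not tested. Of the 24 list calls 0 were made with an estimated correlation, and each omission of 1 array ended some of them. The overlap of 30 genes became 46 with median scaling and lay between 10 and 106 with 1 array left out. All other settings that were run for a count kept it within 1.5 times. The overlap was computed only with median scaling, with the authors' processed values and with 1 array left out. In a fit with 1 array left out, the lone array of a group is assumed to vary like the others.

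No pairing by replicate number was seen: deviations of same-numbered arrays correlated at 0.0377, 0.0764 and -0.056. The labels do not say whether same-numbered samples shared a culture or a day, so pairing cannot be excluded. With the number as a block, 35, 2886 and 2875 genes and 22 lists were called.

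No called gene or list among those named changed direction. Outside the omission of arrays, named genes past the threshold kept their call in 1017 combinations of gene, comparison and setting and lost it in 87. List calls were kept in 116 and lost in 29, of which 24 came from the estimated correlation. With 1 array left out, gene calls were kept in 1293 and lost in 347, and list calls were kept in 114 and lost in 30.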

Other observations

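The tests of gene families were chosen after the data had been seen. Apart from the estimated correlation, no other setting and no omission of an array is reported for them.

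Families of genes that share a symbol stem and have at least 8 tested members were compared with all other genes by camera, 196 families in 3 comparisons. At 60 min against control 8 families passed. Collagen genes were higher: 11 of 24 rose and 0 fell, with a median log2 change of 0.306 (camera adjusted p = 0.000504, and adjusted p = 0.969 with an estimated correlation). COL18A1, COL9A2, COL2A1 and COL5A1 rose by 0.66, 0.65, 0.61 and 0.58. Intraflagellar transport genes, which build cilia, had 8 of 18 higher and 0 lower (median 0.227, adjusted p = 0.0062, and adjusted p = 0.969 with an estimated correlation), with IFT74 and IFT88 at 0.52 and 0.45. Aldehyde dehydrogenase genes had 6 of 16 higher and 0 lower (median 0.205, adjusted p = 0.0213, and adjusted p = 0.969 with an estimated correlation), with ALDH6A1 at 0.50. Against 30 min, 13 of the 24 collagen genes rose and 0 fell (median 0.453, adjusted p = 8.53e-06, and adjusted p = 0.969 with an estimated correlation). Of the 4 fibroblast markers fixed beforehand, 2 also rose in that comparison and 0 fell (2 and 1 adjusted over the list alone; median 0.356, with DCN at -0.47). The 2 were LUM, not above background at 30 min and lost in 2 of 8 settings (adjusted p from 0.0121 to 0.096), and the collagen gene COL3A1 at 0.51, a call lost in 5 of 10 settings (adjusted p from 0.0264 to 0.146). COL3A1 and the marker COL1A1 are also members of the collagen family, so the markers are not separate support for its rise.

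Families of transcription and chromatin regulators were lower at 60 min. ZBTB genes, zinc finger proteins with a BTB domain, had 14 of 38 lower and 2 higher (median -0.24, adjusted p = 0.0062, and adjusted p = 0.969 with an estimated correlation), led by ZBTB34 at -0.65. PHD finger genes had 7 of 16 lower and 0 higher (median -0.239, adjusted p = 0.0062, and adjusted p = 0.969 with an estimated correlation), with PHF13 at -0.48. HOXB genes had 5 of 9 lower and 0 higher (median -0.35, adjusted p = 0.0201, and adjusted p = 0.969 with an estimated correlation), with HOXB13 at -0.64. The other 2 families called, ZNF and RPL, overlap the lists fixed beforehand.

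At 30 min against control 3 families passed. SNORA genes, a class of small nucleolar RNAs, had 3 of 47 lower and 1 higher (median -0.133, adjusted p = 0.0187, and adjusted p = 0.969 with an estimated correlation). SNHG host genes and MRPL genes of the mitochondrial ribosome had 0 members past the threshold among 11 and 49, with medians of 0.11 and 0.0499 (adjusted p = 0.0201 and 0.0328). The adjusted p was 0.969 for both with an estimated correlation.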
